A study of Homo sapiens with 6 samples.

How the data were processed

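RNA of AsPC-1 cells with stable miR-506 overexpression and of vector control cells was labelled with Cy3 and hybridised to Agilent human arrays with 1 colour, per the labels' protocols, 3 arrays per group. The labels describe the RNA as coming from separate cultures. Groups were taken from the labels; replicate numbers follow the order of the samples and pair nothing.

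The scanner files give the intensity of every spot on a linear scale, per the file headers, made with Agilent Feature Extraction 11.0.1.1; the submitters' processing notes name version 10.7.3.1. The processed intensity is background-subtracted and detrended, per the file headers, and is not scaled between arrays. The authors' deposited value table holds log2 values whose median was 5.29 and whose lowest and highest value were 2.32 and 17.2 on all 6 arrays. Its columns correlated between 0.991 and 0.999 with the log2 scanner values of the same arrays, so the scale is log2 and the arrays have one common distribution, with unstated steps; it served as an alternative. All of its columns of samples were used. Brightness, as the 75th percentile signal, ran from 300.1 to 554 and limits what dim probes show; no spot was saturated.

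Each array held 43118 spots that were not controls, of 34127 probes. The log2 processed signal minus the array's 75th percentile was used. Spots marked as non-uniform or as population outliers were set to missing, and spots of 1 probe were averaged. Probes well above background on at least 3 of 6 arrays were kept, which left 21910. The brightest probe represented a gene, which gave 18001 features. Of these, 13989 had a gene symbol and 4012 only the name in the file, and all are called genes below. Probes were named through their RefSeq accession without version, using a table of RefSeq genes for the GRCh38.p14 assembly; 25771 probes (75.5%) matched and the others kept the accession of the file. No genome was used, and because the array annotation follows another build no coordinates are given. Where named genes had more probes, those that disagreed by sign were TSNARE1 and CDH2 (the second CDH2 probe gave -0.36 against 0.20).

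Differences were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, no covariate) with Benjamini-Hochberg adjustment and a threshold of 0.05. Spreads are those between cultures as labelled. Gene lists with at least 5 measured members were tested with camera at its preset correlation of 0.01, over 29 of 30 lists and 17860 genes with values on all arrays, adjusted over lists, beside camera with an estimated correlation and fry. The lists covered reported miR-506 and miR-124 targets, epithelial, mesenchymal, G1/S, G2/M, homologous recombination, sphingolipid, NF-kappaB, autophagy, apoptosis, interferon, p53, cholesterol, hypoxia, stress response, MAPK, YAP/TAZ, mucin and differentiation, integrin and laminin, protease, neuronal, microRNA machinery, histone, ribosomal, respiratory chain, handling, immune, stromal and acinar or islet genes. Older symbols of members were updated through the same table.

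The groups, lists, main fit and most alternatives were fixed before the data were examined. So was the rule for named genes: the 12 largest rises and falls past the threshold with complete separation of the groups and probes well above background on at least 2 arrays of each group, up to 3 genes per direction known by a bound, list members past the threshold and every measured reported miR-506 target. Some genes that these rules select are not reported here. Since 1 gene passed, further genes were named by a rule made after their values were seen: the 12 highest and 12 lowest differences at an unadjusted p under 0.05 with complete separation, the same background limit, and a difference within slide 2 of the same sign and at least 0.5 times the pooled one. The genes given by a bound were chosen after their values were seen too, at an unadjusted p under 0.05 with complete separation and no limit on slide 2; their bounds compare the bright group's mean with the higher of the lowest signal well above background and the dim probe's own signal, per array.

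Alternatives were quantile normalization, normexp background correction (offset 50) with either normalization, no filter and a filter on all 6 arrays, the mean of all probes of a gene, trend and robust eBayes, array weights, the deposited values, slide as a block, and leaving out each array. Normexp used the median signal and median background of each spot in place of the planned mean signal, and genes were named by accession in place of the planned gene name column. Brightness as a covariate and the 4 arrays of slide 2 alone were added after seeing the data. Slides were told apart by the scan recorded in the headers.

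The fit and the list test were tested on simulated data with the real means and spreads of 17860 genes, of which 200 were changed. For 3 arrays against 3, 55.2% of genes changed 2-fold and 82.3% of those changed 4-fold were called, with 7.9 false calls per run over 20 runs. A list of 22 genes shifted by -0.5 was called in 20 of 20 runs, in 18 with an estimated correlation, and 0 of 560 unshifted lists were. Genes varied independently there, so it does not test correlated genes or slides.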

Results

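Messenger RNA levels were measured in AsPC-1 cells, an established human pancreatic cancer line, that stably overexpressed the microRNA miR-506 from a lentivirus, and in AsPC-1 cells with the vector as negative control. MicroRNAs are short RNAs that pair with messenger RNAs and lower their stability or translation. RNA from 3 cultures of each kind was hybridised, 1 culture per array, to 6 Agilent human arrays of 1 colour, and the question was which transcripts differed between the miR-506 cells and the control. miR-506 itself was not probed, so its level was not checked here. The number of arrays limits the precision of every value. Levels are given as log2 signal relative to the array's own 75th percentile, and differences are miR-506 minus control with the standard error (SE) of the limma fit.

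The arrays differed in brightness and lay on 2 slides. The log2 of the 75th percentile signal was 8.91 on miR-506 replicate 1, 9.11 on replicate 2 and 8.29 on replicate 3, against 8.28, 8.23 and 8.62 on control replicates 1, 2 and 3. Between 57.2% and 75.7% of probes were well above background. Replicates 1 and 2 of miR-506 shared slide 1, while miR-506 replicate 3 and the 3 controls shared slide 2. The first principal component took 69.3% of the variance and placed miR-506 replicates 1 and 2 at 53.2 and 52.4. The other 4 arrays lay at -21.7 for miR-506 replicate 3 and at -50.6, -31.4 and -1.8 for the controls. The correlation across genes was 0.994 between miR-506 replicates 1 and 2, but 0.974 between each of them and replicate 3, which correlated at 0.991 with control 2. Values within slide 2, where miR-506 replicate 3 meets the 3 controls, are therefore given beside pooled ones. For genes with values on all arrays a fit with slide as a block gives the same estimates, because slide 1 holds no control. Both therefore compare 1 miR-506 array with 3 controls, and their p values carry no spread between miR-506 cultures within that slide.

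**Figure D1:**
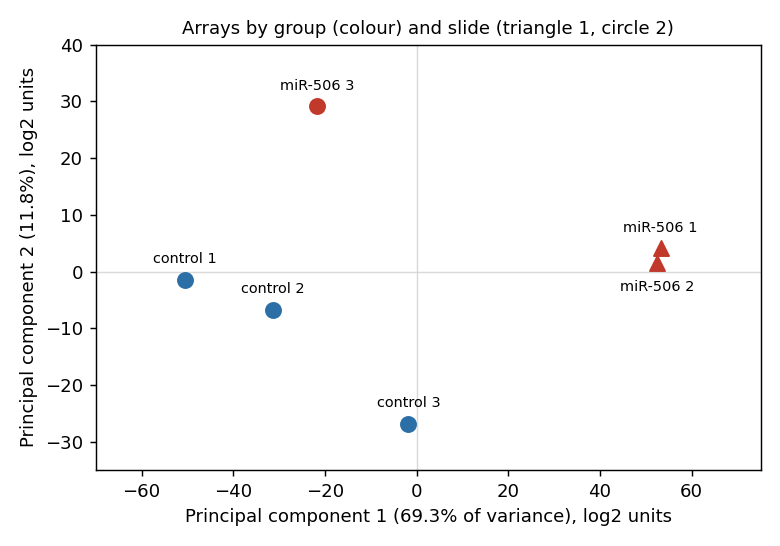
Each point is 1 array, placed by its first and second principal components (log2 units) over all tested genes, with red for miR-506, blue for control, triangles for slide 1 and circles for slide 2. The miR-506 arrays of slide 1 sit at 53.2 and 52.4 on the first component, and miR-506 replicate 3 at -21.7 lies among the controls on that axis and at 29.1 on the second.

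LCN2, which encodes the secreted iron-siderophore carrier lipocalin 2, rose 3.30-fold in the miR-506 cells. Its level was 0.99, 1.16 and 1.15 on the miR-506 arrays against -0.58, -0.70 and -0.61 on the control arrays, with SDs of 0.10 and 0.06, a log2 difference of 1.72 ± 0.09 (SE; limma, adjusted p = 0.0285; RefSeq transcript NM_005564). Within slide 2 the difference was 1.77. It was the 1 gene of 18001 that changed past the threshold. By limma, 1 gene was higher, 0 genes were lower and 1 gene changed at least 2-fold, while 4196 genes (23.3%) had an unadjusted p under 0.05. With slide as a block the LCN2 difference had an adjusted p of 0.139, and 0 genes passed the threshold, with 1753 at an unadjusted p under 0.05. Without miR-506 replicate 3, 2095 genes passed the threshold, 1487 higher and 608 lower. Leaving out any other single array gave 0 calls, and limma's adjusted p of LCN2 then lay between 0.159 and 0.348. It was 0.0542 with normexp background correction, 0.0948 with normexp and quantile normalization and 0.184 with no filter on dim probes.

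MMP1, MMP3, APP and 9 further transcripts were lower on every miR-506 array than on any control array, without passing the threshold. These genes, and the higher ones after them, were chosen after their values were seen. They are the extremes of 1492 lower and 957 higher genes that met the same rule. That rule required the complete separation and a difference within slide 2, so neither is a result about these genes. MMP1 and MMP3, which encode matrix metalloproteinases that cut collagen and other matrix proteins, differed by -1.74 ± 0.21 and -1.78 ± 0.39 on the log2 scale (SE, limma, adjusted p = 0.149 and 0.150), and by -1.73 and -1.30 within slide 2. APP, the amyloid precursor protein gene, differed by -1.73 ± 0.28 (within slide 2, -1.52), although a dimmer probe of the same gene gave -0.61. FAM50B differed by -1.71 ± 0.16 (within slide 2, -1.64). DDIT4, which encodes a stress-induced inhibitor of mTORC1, differed by -1.62 ± 0.28, and RETSAT, a retinol saturase gene, by -1.43 ± 0.13, with -1.59 and -1.51 within slide 2. TP53INP1, a p53-induced gene, differed by -1.30 ± 0.22 and OLR1, the receptor gene for oxidised low-density lipoprotein, by -1.21 ± 0.12, with -1.62 and -1.11 within slide 2. The remaining genes among the 12 lowest were DNER at -1.32 ± 0.25, DHRS2 at -1.29 ± 0.34, the antisense RNA INHBA-AS1 at -1.21 ± 0.25 and TXK at -1.16 ± 0.20. Within slide 2 these differed by -1.72, -1.37, -0.77 and -1.60. Normexp background correction with quantile normalization left APP at -1.66 and DDIT4 at -1.60 but shrank the others. They then lay at -1.15 for MMP3, -1.05 for MMP1, -1.04 for FAM50B, -0.70 for RETSAT, -0.63 for TP53INP1, -0.38 for OLR1, -0.37 for DNER, -0.775 for DHRS2, -0.205 for INHBA-AS1 and -0.11 for TXK. The threshold was passed by all of the 12 with array weights and by all but DHRS2 (adjusted p = 0.0949) without miR-506 replicate 3, at an adjusted p of 0.0193 for MMP1, 0.0276 for APP and at most 0.0381. Of all 18001 genes, 4852 passed with array weights and 2095 without miR-506 replicate 3, so passing there does not mark these 12. Leaving out that array sets slide 1 against slide 2. The array weights do so in large part, as they gave miR-506 replicate 3 a weight of only 0.289.

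Apart from LCN2, the 12 highest genes were likewise chosen by a rule that required a difference within slide 2. On miR-506 replicate 3 these genes lay between the other miR-506 arrays and the controls. CTRL, a chymotrypsin-like pancreatic protease gene, differed by 1.71 ± 0.42 over all arrays and by 0.88 within slide 2. TMEM72 differed by 1.75 ± 0.49 and 0.89, VWA5A by 1.62 ± 0.33 and 0.88, and TOMM20L by 1.58 ± 0.28 and 1.01. SYCE3, a gene of the meiotic synaptonemal complex, differed by 1.46 ± 0.27 and by 1.19 within slide 2. With normexp background correction and the 75th percentile SYCE3 differed by only 0.29, PRRT1 by 0.49 in place of 1.35, VWA5A by 0.73 and TMEM72 by 1.05. With brightness as a covariate TMEM72 differed by 0.97 and CTRL by 1.04. SBK3, LILRA1, PRRT1, PSD and TSNARE1 were also among the 12, and of TSNARE1 a second, dim probe gave -0.16. None of these genes but LCN2 passed the threshold in limma with all arrays. With array weights all named here passed, and without miR-506 replicate 3 all but SBK3 and PRRT1 (adjusted p = 0.0887 and 0.0551). Of all 18001 genes, 4852 and 2095 passed in these settings. Some transcripts were well above background in 1 group and on no array of the other, where only a bound can be given. TXNDC2 was at least 3.71-fold, KRTAP2-2 at least 3.05-fold and LCN12 at least 2.56-fold higher in miR-506 cells, and LINGO1 was at least 2.14-fold, CTSS, the cathepsin S gene, at least 1.88-fold and the antisense RNA PAX6-AS1 at least 1.58-fold lower. Their limma adjusted p lay between 0.149 and 0.179. These bounds allow for the dim signal only and not for the spread between arrays, so they are no lower limits on the difference between the cells. The bounds within slide 2 were at least 2.10-fold for TXNDC2, 3.84-fold for KRTAP2-2 and 1.70-fold for LCN12 higher, and at least 1.44-fold for LINGO1, 1.26-fold for CTSS and 1.06-fold for PAX6-AS1 lower.

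**Figure D2:**
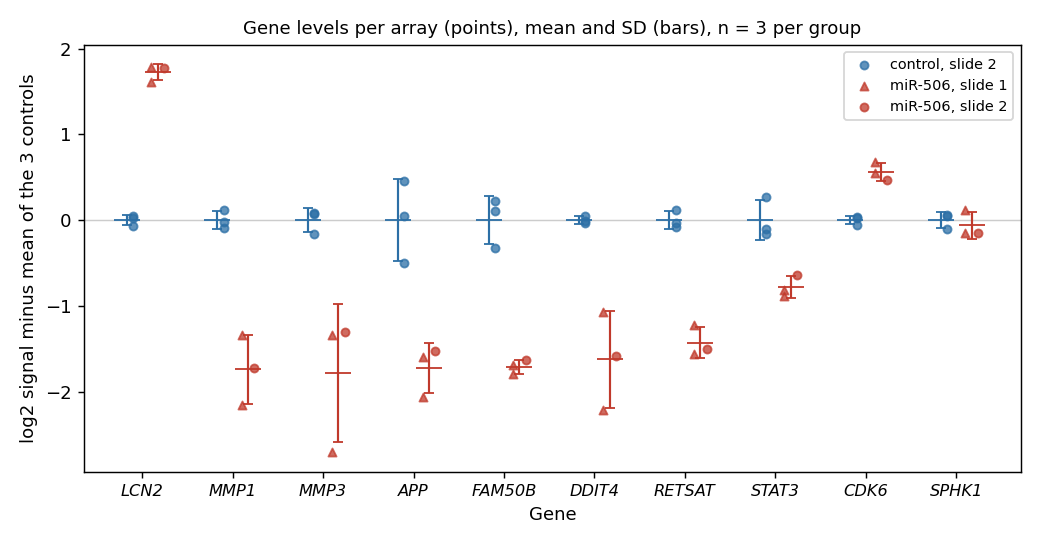
Each point is the log2 signal of 1 gene on 1 array minus the mean of the 3 controls, with red for miR-506, blue for control, triangles for slide 1 and circles for slide 2, and horizontal marks and bars for the mean and SD of 3 arrays. LCN2 lies at a mean of 1.72 on the miR-506 arrays, MMP1 at -1.74 and SPHK1 at -0.06.

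SPHK1, the sphingosine kinase 1 gene that has been reported elsewhere as a target of miR-506 in pancreatic cancer, did not differ detectably. Its level was 1.51 ± 0.16 (SD, n = 3) in miR-506 cells and 1.58 ± 0.09 (SD, n = 3) in control cells, a log2 difference of -0.06 ± 0.12 (SE; limma, adjusted p = 0.752; within slide 2, -0.16). The 95% interval of the difference ran from -0.34 to 0.22. Of the 17 measured transcripts reported elsewhere as miR-506 targets, 0 passed the threshold over all genes, and 11 lay lower and 6 higher. Without miR-506 replicate 3, which leaves slide 1 against slide 2, STAT3, PIM3 and CDK6 passed (adjusted p = 0.0334, 0.0368 and 0.0270), and with array weights IQGAP1 and SNAI2 as well (adjusted p = 0.0446 and 0.0438). Of all 18001 genes, 2095 and 4852 passed in these settings. Adjusted over the list alone, CDK6 was higher and STAT3 and ETS1 were lower. STAT3, a transcription factor activated by cytokines, differed by -0.78 ± 0.15 (SE, and -0.64 within slide 2), although its second probe gave -0.37. ETS1 differed by -0.48 ± 0.11 (within slide 2, -0.54), PIM3 by -0.42 ± 0.15 (-0.13) and YAP1 by -0.30 ± 0.11 (-0.22). Against the direction of a target, CDK6, a G1 cyclin-dependent kinase gene, differed by 0.56 ± 0.10 (within slide 2, 0.47) and SNAI2 by 0.61 ± 0.22 (0.60), although SNAI2 was at 0.07 with normexp and the 75th percentile. Differences of other members were 0.32 for IQGAP1, 0.20 for CDH2, 0.04 for VIM, 0.03 for EZH2, -0.05 for ROCK1, -0.07 for GLI3, -0.10 for CDK4, -0.19 for FOXM1 and -0.29 for FLOT1. Within slide 2 these were 0.12 for IQGAP1, 0.34 for CDH2, -0.05 for VIM, -0.19 for EZH2, 0.08 for ROCK1, -0.02 for GLI3, -0.18 for CDK4, -0.11 for FOXM1 and -0.13 for FLOT1. The median of the list was -0.07 (within slide 2, -0.11), which camera did not separate from other genes (adjusted p = 0.333). The median was -0.18 with quantile normalization alone and -0.14 without miR-506 replicate 2. With normexp and quantile normalization the list passed, at a median of -0.27 (camera, adjusted p = 0.0417), and camera with an estimated correlation gave an adjusted p of 0.594 in the main setting. The 23 reported targets of miR-124, a microRNA with the same seed, had a median of -0.10 overall and within slide 2 (camera, adjusted p = 0.215). Adjusted over that list alone, 1 was higher and 3 were lower. STAT3, SNAI2, CDK4, CDK6, EZH2, IQGAP1 and FLOT1 are on both lists, so the lists are not separate evidence.

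Genes of cholesterol synthesis and uptake were lower in the miR-506 cells as a list. All 22 measured members had a negative difference, with a median of -0.65 on the log2 scale (camera with preset correlation, adjusted p = 2.2e-08). The call was lost at an adjusted p = 0.594 with an estimated correlation, and fry gave an adjusted p of 0.103. By single genes 0 passed the threshold over all genes, and 13 were lower adjusted over the list alone. Without miR-506 replicate 3, MVD, SC5D and ACAT2 passed over all genes (adjusted p = 0.0468, 0.0458 and 0.0411), where 2095 of 18001 genes did. MVD, of the mevalonate pathway, differed by -1.11 ± 0.21 and MSMO1, a sterol oxidase gene, by -1.05 ± 0.32. FDFT1, the squalene synthase gene, differed by -0.77 ± 0.19. For MVD, MSMO1 and FDFT1 the differences within slide 2 were -1.13, -0.89 and -0.61. The mean of the list against the controls was -1.08, -0.28 and -0.59 on miR-506 replicates 1, 2 and 3, and between -0.03 and 0.03 on the controls. Without miR-506 replicate 1 the median was -0.43. The median within slide 2, from 1 miR-506 array, was -0.57. With slide as a block, which rests on that same array, camera called the list too (adjusted p = 1.1e-06), which adds no second culture in support.

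The preset-correlation camera test also placed 6 further lists lower and 1 higher. None of these 7 calls, nor that for cholesterol, held with an estimated correlation, where the adjusted p of the 7 lay between 0.486 and 0.653. NF-kappaB target genes had a median of -0.47 (adjusted p = 0.00535), with SOD2 at -0.81 ± 0.18 and the adhesion gene ICAM1 at -0.69 ± 0.16, while LCN2, itself a member, rose. The mean of this list against the controls was -0.75, -0.06 and -0.22 on miR-506 replicates 1, 2 and 3, and without miR-506 replicate 1 its median was -0.20. MAPK output genes had a median of -0.24 (adjusted p = 0.00467), with PHLDA1 at -0.64 ± 0.12 and the transcription factor gene EGR1 at -0.78 ± 0.18, and a median of -0.16 without miR-506 replicate 1. Genes of the unfolded protein and integrated stress responses had a median of -0.28 (adjusted p = 0.00324), with CHAC1 at -1.06 ± 0.24 beside DDIT4. For p53 target genes the median was -0.16 (adjusted p = 0.00682), and it was -0.40 with brightness as a covariate and -0.09 with normexp and quantile normalization, with the cell cycle inhibitor gene CDKN1A at -0.69 ± 0.13 and the pro-apoptotic BBC3 at -0.82 ± 0.14. Autophagy and lysosome genes had a median of -0.14 (adjusted p = 0.00467), or -0.22 with normexp and quantile normalization, with the receptor gene SQSTM1 at -0.75 ± 0.13 and the kinase gene ULK1 at -0.96 ± 0.20. Matrix protease and inhibitor genes had a median of -0.23 (adjusted p = 0.0228), and MMP1 and MMP3 are among its members. With no filter on dim probes that median was -0.01 and the call ended (adjusted p = 0.122). G2/M and mitosis genes lay higher, with a median of 0.19 (adjusted p = 0.0109), PTTG1 at 0.84 ± 0.17 and CCNB1 at 0.44 ± 0.10. Differences within slide 2 were -0.85 for SOD2, -0.69 for ICAM1, -0.59 for PHLDA1, -0.74 for EGR1, -0.82 for CHAC1, -0.52 for CDKN1A, -0.80 for BBC3, -0.72 for SQSTM1, -1.05 for ULK1, 0.63 for PTTG1 and 0.39 for CCNB1.

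By list, camera's adjusted p with an estimated correlation was 0.653 for NF-kappaB, 0.598 for G2/M and 0.486 for the stress responses and p53. It was 0.594 for the MAPK, autophagy and protease lists. The correlations so estimated were 0.662 for cholesterol, 0.546 for NF-kappaB, 0.241 for G2/M and 0.184 for proteases. They were 0.115 for MAPK, 0.088 for autophagy, 0.033 for the stress responses and -0.025 for p53. As the p53 value lies below the preset 0.01, a higher correlation did not end that call. Adjusted p values of fry, which tests whether a list moves on balance in 1 direction, were 0.00939 for p53, 0.0422 for MAPK and for the stress response lists and 0.0439 for autophagy, but 0.547 for NF-kappaB, 0.0958 for proteases and 0.103 for G2/M. Of single genes, only LCN2 passed over all genes. Among the members named above, without miR-506 replicate 3 and besides MMP1, MMP3 and DDIT4, PHLDA1, CHAC1, CDKN1A, BBC3, SQSTM1 and PTTG1 passed as well (adjusted p = 0.0397, 0.0439, 0.0287, 0.0363, 0.0380 and 0.0319). In that setting, slide 1 against slide 2, 2095 of 18001 genes passed. Adjusted over the list alone, 7 MAPK, 6 p53, 4 NF-kappaB, 4 protease, 3 stress response and 2 autophagy genes were lower, 2 NF-kappaB genes were higher, and 0 G2/M genes passed. Within slide 2 the medians were -0.28 for NF-kappaB, -0.33 for MAPK, -0.20 for the stress responses, -0.31 for p53, -0.10 for autophagy, -0.29 for proteases and 0.24 for G2/M. With slide as a block the camera call ended for autophagy (adjusted p = 0.107) and NF-kappaB (adjusted p = 0.120). With normexp background correction it ended for NF-kappaB, MAPK and p53 (adjusted p = 0.0554 each) and proteases (adjusted p = 0.155). The protease call also ended with normexp and quantile normalization (adjusted p = 0.0527) and with array weights (adjusted p = 0.0935). The G2/M call ended without miR-506 replicate 3, control 2 or control 3 (adjusted p = 0.158, 0.0558 and 0.0801), and the protease call without miR-506 replicate 3 or control 3 (adjusted p = 0.158 and 0.0833).

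**Figure D3:**
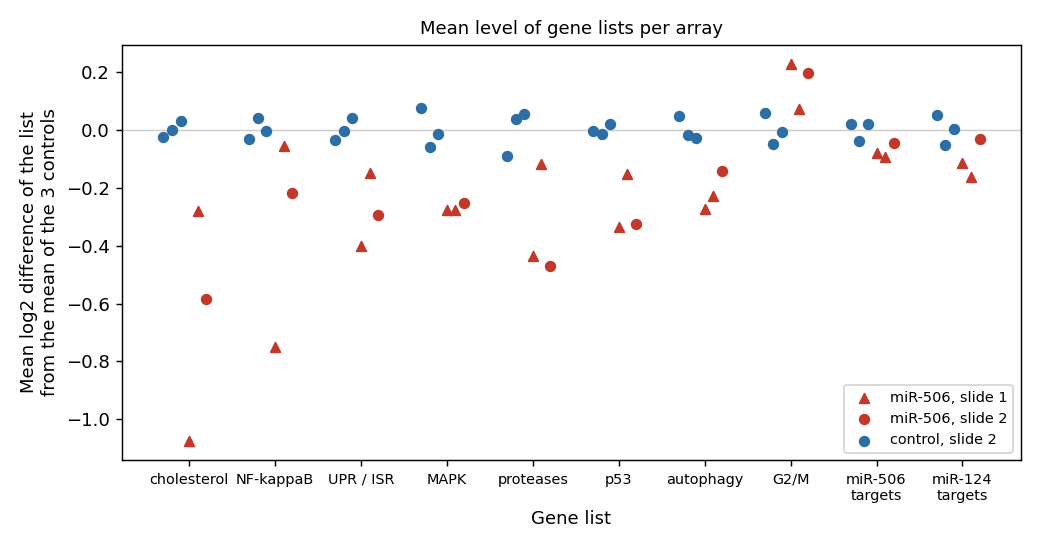
Each point is the mean log2 difference of the genes of 1 list on 1 array from the mean of the 3 controls, with red for miR-506, blue for control, triangles for slide 1 and circles for slide 2. The cholesterol list lies at -1.08, -0.28 and -0.59 on the miR-506 arrays, and the list of reported miR-506 targets between -0.09 and -0.05.

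Lists of other cell types and of sample handling were not called. The 7 measured immune cell markers had a median difference of 0.79 (camera, adjusted p = 0.228), which was -0.06 within slide 2. Their mean against the controls was 0.81 and 1.01 on miR-506 replicates 1 and 2, -0.01 on miR-506 replicate 3 and 0.51 on control 3. Of the fibroblast and endothelial markers 2 were measured, too few for the list test. The 12 immediate early and heat shock genes had a median of 0.04 and a mean of -0.04 (camera, adjusted p = 0.936), with a median of 0.11 within slide 2. The 5 measured acinar and islet markers had a median of 0.03 (camera, adjusted p = 0.926), and of 0.01 within slide 2.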

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

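The control probe ETG09_35454, which the comparisons do not use and whose target is not given in the sources used here, gave a signal on slide 1 above that of the control arrays. Its level was -4.83 and -4.01 on miR-506 replicates 1 and 2, the 2 arrays of slide 1, where it was well above background. It was not well above background on slide 2, neither on miR-506 replicate 3 (-6.54) nor on the controls (-6.88, -6.55 and -6.91). The mean difference that picked it out, 1.65 on the log2 scale, is therefore no measured size, and as slide 1 holds no control it does not tell the miR-506 cells from the slide. That unused control probes were searched without a limit on dim probes was decided after seeing the data.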

How the results depend on the processing

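Brightness as a covariate and slide 2 alone were chosen after seeing the data; the other alternatives were fixed beforehand. The number of genes changed, 1 in the main setting, stayed at 1 with quantile normalization, the deposited values, the filter on all 6 arrays, the mean of all probes, and trend and robust eBayes. With normexp and the 75th percentile, normexp and quantile normalization, no filter on dim probes, slide as a block, brightness as a covariate, and only the slide with both groups, 0 genes changed, 0 changed at least 2-fold and 0 were higher; limma's unadjusted p was under 0.05 for 4032, 4085, 4457, 1753, 2938 and 1591 genes. The unfiltered fit tested 27708 features, and slide 2 alone has 4 arrays; otherwise the cause was not tested. With array weights 4852 genes changed, 1257 at least 2-fold, 2825 higher and 2027 lower; the weight was 0.289 for miR-506 replicate 3 and 4.21 for control 2. Leaving out 1 array at a time gave 0 to 2095 genes changed, 0 to 1063 at least 2-fold, 0 to 1487 higher and 0 to 608 lower, all upper values without miR-506 replicate 3. LCN2 kept its direction in all 18 alternatives, between 1.37 and 1.78, with adjusted p from 0.00515 to 0.427. SPHK1 stayed between -0.16 and -0.02 and passed in 0 of them.

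The number of lists shifted was 8, between 6 and 9 over those 18 alternatives, and 0 with camera's estimated correlation. Cholesterol and the stress responses passed in all 18 (highest adjusted p 1.9e-05 and 0.0337), MAPK and p53 in 17, NF-kappaB and autophagy in 16, G2/M in 15 and proteases in 12. Signs turned for some reported targets that passed in no such setting. VIM, 0.043 in the main setting, was -0.177 with quantile normalization, -0.013 with normexp and the 75th percentile, -0.273 with normexp and quantiles, -0.181 with the deposited values, -0.052 with slide as a block and on slide 2 alone, and -0.039 with brightness. EZH2, 0.029 in the main setting, was -0.023, -0.058, -0.148, -0.021, -0.191 and -0.161 in the same order, and -0.053 to 0.139 when arrays were left out. CDH2, 0.201 in the main setting, was -0.079 with the mean of its probes, because its second probe gave -0.36. ROCK1 was 0.083 with slide as a block and on slide 2 alone and 0.05 with brightness. For VIM, EZH2 and ROCK1 the cause was not tested. Of 716 values of named genes in the alternatives 633 kept direction and side of the threshold, 11 lost it, 52 gained it and 20 turned sign. For all named genes but LCN2, keeping the side meant staying uncalled, so the 633 do not measure how stable calls were. The 11 losses were all of LCN2, the only call, in 11 of the 18 alternatives.

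No paired analysis was possible because the groups share no replicate numbers in the labels. The tests of seed sites in 3′ untranslated regions, with their alternatives, were not run, since no genome was used here. Signal over background limits the dim probes: 57.2% to 75.7% of probes were well above it.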

Other observations

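Outside the lists described so far, several groups held genes that moved apart from each other, and none of these lists was called by camera at the preset correlation. Of 23 apoptosis genes 6 were lower and 2 higher adjusted over the list alone, with a median of -0.17, which was -0.06 within slide 2 (camera, adjusted p = 0.225). MCL1, which encodes an anti-apoptotic protein, differed by -0.70 ± 0.14 (SE) and the death receptor gene TNFRSF10A by -0.56 ± 0.11, while the anti-apoptotic BCL2L1 differed by 0.37 ± 0.09 and BIRC5 by 0.34 ± 0.09; within slide 2 these were -0.57, -0.45, 0.44 and 0.42. Of 19 hypoxia and glycolysis genes 4 were lower and 2 higher adjusted over the list alone (median -0.15, within slide 2 -0.09, adjusted p = 0.0785). NDRG1 differed by -0.55 ± 0.11 and HK2 by 0.40 ± 0.09, and within slide 2 by -0.45 and 0.47. Of 21 YAP/TAZ target genes 3 were higher and 1 lower adjusted over the list alone. The list's median was 0.16 (camera, adjusted p = 0.228), but 0.04 within slide 2 and 0.01 with brightness as a covariate. FJX1 lay at 0.74 ± 0.15 and NUAK2 at 0.62 ± 0.13, and within slide 2 at 0.46 and 0.45. Of 16 mesenchymal genes 2 were lower adjusted over the list alone. That list had a median of 0.09 and a mean of 0.14, while camera pointed down at an adjusted p of 0.936. S100A4 lay at -0.85 ± 0.18 and within slide 2 at -0.63. Of 18 epithelial genes 0 passed adjusted over the list alone (median 0.12, within slide 2 0.02, camera, adjusted p = 0.246). EPCAM lay at 0.46 ± 0.10 and within slide 2 at 0.38. These genes were picked after their values were seen.

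The mucin and differentiation list had a median of 0.21 (adjusted p = 0.735), which was -0.33 within slide 2; TFF1 differed by 1.09 ± 0.24 and GATA6 by -0.48 ± 0.10, and within slide 2 by 0.60 and -0.52. Camera's adjusted p was 0.830 for G1/S (median -0.02), 0.936 for homologous recombination (median -0.02, mean 0.03), 0.217 for sphingolipid (median -0.14), 0.735 for interferon (median 0.03, camera pointed down), 0.247 for integrin and laminin (median -0.10), 0.865 for neuronal (median 0.12), 0.865 for microRNA machinery (median 0.04), 0.272 for histone (median 0.17), 0.735 for ribosomal (median 0.03) and 0.964 for respiratory chain genes (median 0.04). Medians of these lists within slide 2 were 0.06, 0.14, -0.16, -0.13, -0.05, -0.04, -0.03, 0.04, 0.03 and 0.05 in the same order.

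In the paragraphs on patterns below, the test of brightness on dim probes and that of a weaker response were set before their results were seen, the others, and the look at control probes, only afterwards. The 6 arrays make 10 splits into 3 and 3, too few for a share under 0.05. As many changed genes as the real split, 1, came in 2 of the 10 splits, also for genes changed at least 2-fold and for genes higher; the highest of the other splits gave 445, 301 and 414. For genes lower, the real split gave 0, which all 10 reached, and the highest other, in either direction, was 414. For lists shifted the real split gave 8 and was the 1 split to reach that, with 4 the highest of the others. The split with 445 genes put control 3 with miR-506 replicates 1 and 2, which points to a structure of the samples other than the groups; the values with slide as a block are 0 genes and 6 lists.

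The first pattern is that miR-506 replicates 1 and 2 stood apart from the other 4 arrays. Without miR-506 replicate 3, 2095 genes were called, and SOX8, a transcription factor gene, was 4.80 higher on the log2 scale (0.04 within slide 2), GNG13 3.50 higher (0.22) and CPB1, a pancreatic carboxypeptidase gene, 3.04 higher (0.14). Of the 2095 genes, 1063 were at least 2-fold apart, and 1053 of those entered the next comparison. Over these, miR-506 replicate 3 lay at a median of 0.09 of the way from the controls to replicates 1 and 2. This is within the range of the controls themselves (-0.25 to 0.24). A difference between slides could give this, and slide 1 holds no control. The control probe ETG05_36762 was well above background on these 2 arrays, at -4.02 and -4.41, and not on slide 2. A weaker response of culture 3 stays open. At most 8.0% of the 1053 genes had over 0.75 of the difference in it, which met the limit of at most 20% set beforehand for such a response. Its median share ran from -0.05 to 0.27 depending on the control taken as base. That check was added afterwards, and because of it the response was left undecided. Brightness acting on dim probes stays open too. Of the 2095 called genes, 450 (21.5%) were in the brightest part of 3 equal parts and 875 in the dimmest. By the limit set beforehand, a share over 20% in the brightest part would count against brightness, and 21.5% met it. That limit named no interval, and the 95% exact binomial interval (19.7 to 23.3) reached below 20%. The interval treats genes as independent draws, which genes of the same arrays are not. The share therefore decides neither way.

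The second pattern is the lower level of the cholesterol genes. With brightness as a covariate the list had a median of -0.69 (camera with preset correlation, adjusted p = 2.7e-08), which argues against brightness as its whole cause. It does so mainly through miR-506 replicate 3, because the 2 arrays of slide 1 were also the brightest (8.91 and 9.11). For the same reason the 518 genes that followed brightness past the threshold may follow the slide. In miR-506 replicate 3, 21 of the 22 genes were lower than in all 3 controls on its slide. That is 1 array, so slide and group cannot be told apart for the other miR-506 arrays. A response of the cells to miR-506 may therefore account for it, as may a difference between cultures in medium or density, which was not tested; the list's call also ended with an estimated correlation.

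The third pattern is that control 3 lay nearest to miR-506 replicates 1 and 2 among the arrays of slide 2, and miR-506 replicate 3 among the controls. Swapped labels of these 2 arrays could give this. The labelled split parted 157 genes by over 0.5 on the log2 scale and the swapped split 639, while the highest of the other 8 splits parted 20. Most of those 8 divide miR-506 replicates 1 and 2, which share a slide, and so could part few genes. The splits that kept them together, with control 1 or control 2, parted 20 and 13. Few such splits exist and the rule was made after the values were seen, so the count does not decide on a swap. In the swapped split 602 genes were higher and 37 lower with control 3 beside miR-506 replicates 1 and 2. In the labelled split 74 were higher and 83 lower in miR-506. The cholesterol list, singled out by the labelled split, had a mean of -0.59 on miR-506 replicate 3 and 0.03 on control 3. The immune cell markers went the other way, at -0.01 and 0.51. With no limit on the gap, the labelled split parted 5391 genes (30.2%) and the swapped split 5498 without overlap. The splits with control 1 or control 2 beside miR-506 replicates 1 and 2 parted 1131 and 953, and the highest of the other 8 was 1304. Chance gives 10% only if all arrays are alike, which those of 2 slides were not. This is the same comparison at another cut-off, so it does not decide on a swap either. The array's bright corner control probe followed the swapped split: its level was 2.84 and 3.53 on miR-506 replicates 1 and 2 and 2.57 on control 3, against 1.27 on miR-506 replicate 3 and 0.24 and 1.28 on the other controls. Control 3 was also the brightest array of slide 2, with a log2 of the 75th percentile signal of 8.62. It was 8.29 on miR-506 replicate 3 and 8.28 and 8.23 on controls 1 and 2, against 8.91 and 9.11 on miR-506 replicates 1 and 2. What set control 3 apart stays open, brightness or another technical difference between the arrays included.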
